A study of Atriplex prostrata and Atriplex rosea and Atriplex prostrata x Atriplex rosea with 87 samples.

How the data were processed

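Gene expression was measured by RNA sequencing of whole leaves and leaf parts of Atriplex prostrata, a species with C3 photosynthesis, Atriplex rosea, a species with C4 photosynthesis, and their F1 hybrid. Per the labels' protocols, plants grew at 27 °C by day and 22 °C by night with 17 h of light at 500 µmol m-2 s-1 and 7 h of darkness, and leaves were collected 2 h after the lights came on. Leaves longer than 10 mm were divided into a bottom and a top part. Leaves of the different plants were matched by leaf plastochron index, a developmental age computed from leaf lengths. The labels state that 12 libraries shared a sequencing lane and that reads were 100 or 150 bp long, without saying which libraries shared a lane. Possible lane effects could therefore not be separated from the groups.

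The authors deposited 1 table with a read count per library for each Arabidopsis thaliana locus. The deposited table also holds RPM values (reads scaled to the library total) and, for 6 stages, the authors' own log2 fold changes and q-values between the species. Per the submitters' processing notes, CASAVA, DESeq2 and the TAIR10 release of the Arabidopsis genome were used, with no versions given. The aligner and the counting program are not given in the sources used here. The counts of both Atriplex species thus stand for reads assigned to loci of another plant family. A locus can be low in 1 species because its reads match Arabidopsis less well, and reads of 1 Atriplex gene can be spread over several Arabidopsis paralogs. In the counts used here, 65 tested loci in 31 groups had the same count as another locus in every library, so members of such groups and of close families are uncertain as single genes. Nothing states whether strand was used in counting. The table names loci by identifier and symbol and gives no coordinates, so none are reported.

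The table lists 21976 loci. In 5 of them (CRY2 AT1G04400, PSAG AT1G55670, AT3G29590, AT5G54060 and AT5G56290) the values had moved out of their columns, and these loci were left out. The remaining 21971 loci, 88 of them plastid and 122 mitochondrial, formed the library totals. The deposited RPM was recomputed from the counts for 1054608 pairs of locus and library, and in 0 of them did the values differ by more than 1% and 0.5 RPM. Of the 60 count columns, 48 could be matched to labelled samples, in 16 groups of 3 libraries. The other 12 count columns match no label unambiguously and were not used. The labels list 87 samples, including 27 of the F1 hybrid; the hybrid was not analysed here, and neither were the oldest leaves at index 1.5. The comparisons planned for index 1.5 were therefore made at index 0.8, the oldest age with mapped columns, and the comparison of leaf parts averaged indices 0.3 and 0.8.

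Totals ranged from 7647689 to 15360702 counts per library. A locus with 0 counts in a group was given a floor of 3 counts over that group, and its fold is written as a lower bound; such bounds cover counting error only. No fold is given where a group held 1 to 3 counts, nor for a comparison averaged over groups of which 1 held 0 to 3 counts of the locus. Replicates are separate samples per the labels, which do not say whether they came from separate plants or trays, so p-values measure the spread between these samples. The columns of the leaf 9 samples are numbered 1 to 3 and their labels 3 to 5, so they were matched as a group and the replicate numbers of leaf 9 are uncertain.

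Counts were fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 48 libraries, trimmed mean of M-values (TMM) scaling and the default filter on low counts, which left 14779 loci. The biological coefficient of variation was 15.7%, and the quasi-likelihood fit had 32 residual and 6.1 prior degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood F test, p-values were adjusted by the Benjamini-Hochberg method over all loci tested, and a locus was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Levels are in CPM, counts scaled to the TMM-adjusted library total, as mean ± SD over libraries. TMM factors ran from 0.653 to 1.313 and were lower in older leaves. On the TMM scale the median log2 fold change of all loci lay between -0.074 and 0.013 in every comparison. With library totals instead it was -0.58 in the change with age in prostrata, -0.75 in that in rosea, -0.17 between the species over the stages, -0.19 between the species in mature tips, -0.16 in the difference of the age changes, and -0.12 and -0.14 between the leaf parts of prostrata and rosea. Changes reported here are relative to the TMM scale.

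The 18 gene lists, with 326 Arabidopsis loci, were fixed before the data were examined; 261 of these loci were in the table and 259 were tested. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists. For every list the number of members called is given over all loci tested; counts with p-values adjusted over the list alone were equal except where a different count is given. The rule for naming genes was fixed then too: the 10 loci with the largest change in each direction among those called with a mean of at least 10 CPM on the higher side and, between a pair of groups, no overlap of their libraries; up to 4 members of each list with the largest change; and PPC2, PPDK, NAD-ME1, NAD-ME2, BCA1, RBCS1A, RCA, BASS2, DIC1 and CYCB1;1. GLDP1, also on that list, was not analysed here. Not every gene that meets this rule is reported here. Further list members are named where a count was small or where another scaling ends their call, and these names, like those of loci shared by both species' leaf parts, were chosen after their values were seen.

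On simulated counts for the species contrast over all stages, with 14630 genes in the fit, the test recovered 100 of 100 genes changed 3-fold and 99 of 100 changed 8-fold, with 3 calls among unchanged genes. For the 1 mm contrast it recovered 86 of 100 and 97 of 100 with 3 false calls, and for the leaf parts of prostrata 94 of 100 and 98 of 100 with 1 false call. The simulated noise was drawn separately for each gene, without shifts shared by the genes of a library. These counts of false calls therefore do not cover such shifts. Camera at the preset correlation, run on 100 lists of 20 simulated genes, found the 1 changed list and called 0 others. The simulated genes were independent and the unchanged lists random, so this says nothing about lists whose genes are correlated. Principal components were computed from log2 CPM with a prior count of 2. Every pair of the 48 libraries was compared by a chi-square test of homogeneity over loci with at least 20 counts in the pair, given per degree of freedom. A library drawn again from its own counts gave 1.01 in simulation, and one with 200 genes changed 3-fold gave 12.0.

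Alternatives fixed at the same time were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2's size factors and library totals in place of TMM, no filter on low counts, a filter of 10 CPM in 3 libraries, leaving out the 50 loci with the highest mean, a fit of only the groups compared, a replicate block, the adjusted p alone as threshold, and leaving out each replicate. Leaving out single libraries in the comparisons of leaf parts and of the age changes was added after seeing the data, as were the comparison of libraries by pairs, a block by the column number in the comparison of leaf 9 with leaf 10, and a test of families of loci that share a description. Tables were handled in Python 3.11.15.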

Results

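Leaf transcriptomes of a C3 and a C4 species of the same genus were compared along leaf development. In C3 plants Rubisco fixes carbon dioxide directly, while in C4 plants phosphoenolpyruvate carboxylase fixes it first and a decarboxylase releases it near Rubisco in the bundle sheath. The libraries came from Atriplex prostrata (C3) and Atriplex rosea (C4), with 24 libraries per species in 8 matched groups of 3. Whole leaves were sampled at leaf plastochron indices of -1.3 (1 mm), -0.7 (5 mm) and -0.35 (7.5 mm, leaf 9 and leaf 10 separately). Bottom and top parts were sampled at index 0.3 (15 mm leaves of prostrata, 11 mm leaves of rosea) and 0.8 (18 mm and 13 mm). Library totals ran from 8028511 to 12387428 counts in prostrata (median 9495920) and from 7647689 to 15360702 in rosea (median 10838174). Of the 21971 loci, 5037 had no count in any of these libraries. The F1 hybrid of the species was not analysed here.

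Libraries grouped by species and by age. The first principal component held 50.4% of the variance and separated the species, and the next one held 24.5% and followed leaf age. Spearman correlations between replicates of a group had a median of 0.989 and ran from 0.948 to 0.997. Libraries of 1 species from different groups had a median of 0.965, and libraries of the same stage from both species 0.921. In a chi-square test of counts between libraries, where a value of 1 per degree of freedom is sampling noise, replicates of a group had a median of 16.0 and ran from 1.21 to 105 per degree of freedom. The lowest value among replicates was that of replicates 1 and 2 of 1 mm prostrata leaves, whose other pairs stood at 1.97 and 2.22. The lowest of all 1128 pairs, 1.15, joined 15 mm bottom replicate 1 and 15 mm top replicate 1 of prostrata.

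**Figure D1:**
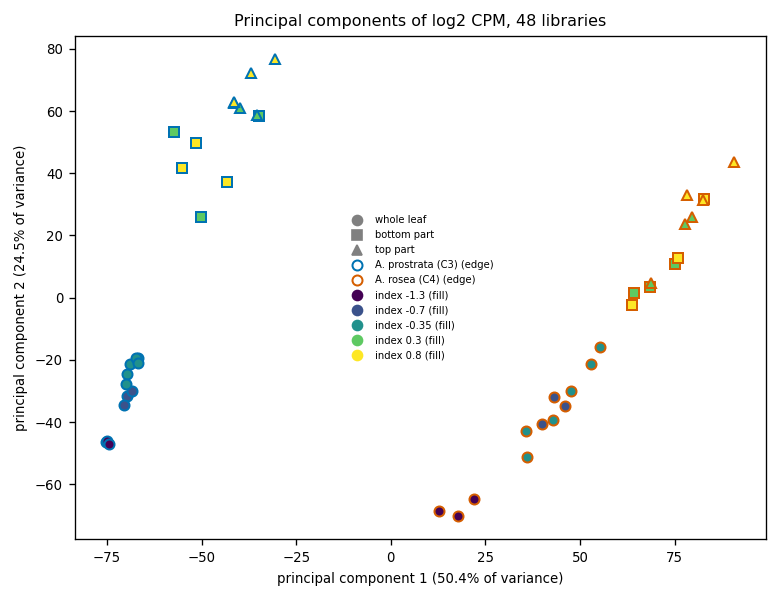
Principal components 1 (50.4% of variance) and 2 (24.5%) of log2 CPM for the 48 libraries; each point is 1 library, with the edge colour giving the species, the fill the leaf plastochron index and the shape the leaf part. Prostrata libraries lie on the left and rosea libraries on the right, with 1 mm leaves at the bottom and divided leaves at the top.

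To ask which transcripts differ between the C4 and the C3 species whatever the leaf age, rosea was compared with prostrata over the 8 matched stages. Genes of the C4 cycle were higher in rosea. PPC2 (AT2G42600), encoding a phosphoenolpyruvate carboxylase, stood at 7553 ± 5270 CPM in rosea and 561 ± 109 CPM in prostrata (SD over stages and replicates, n = 24 each), a log2 fold change of 3.35 (SE 0.12, adjusted p = 2.3e-25). PPDK (AT4G15530), which regenerates phosphoenolpyruvate, was higher by 4.91 (SE 0.13, adjusted p = 2.04e-29) on the log2 scale. The mitochondrial decarboxylases NAD-ME1 (AT2G13560) and NAD-ME2 (AT4G00570), which release carbon dioxide in C4 plants of the NAD-malic enzyme type, were higher by 3.72 (SE 0.10) and 3.08 (SE 0.09).

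Of the 26 tested C4 cycle enzymes, 16 were higher in rosea and 0 lower. The alanine aminotransferase ALAAT1 (log2 fold change 4.48), the aspartate aminotransferase ASP4 (4.41) and the PPDK regulatory protein RP1 (4.39) changed most after PPDK, and the carbonic anhydrase BCA1 (AT3G01500) was higher by 1.68 (SE 0.14). The NADP-malic enzyme loci NADP-ME1, NADP-ME2 and NADP-ME4 were at -0.28, -0.30 and -0.25 and were not called; close paralogs of this kind are uncertain as single loci. Among 10 transporters of C4 metabolites 8 were higher, among them the plastid pyruvate carrier BASS2 (AT2G26900, 3.50, SE 0.09), the mitochondrial dicarboxylate carriers DIC1 (AT2G22500, 2.79, SE 0.13) and DIC2 (2.35), and the phosphoenolpyruvate translocator PPT1 (2.18). Among 16 genes of cyclic electron transport 12 were higher, led by the NDH complex subunits NDHL (3.90), PNSL2 (3.18), PNSB3 (3.06) and PNSL3 (2.94). Camera with the preset correlation called 5 lists: C4 cycle enzymes (adjusted p = 5.18e-11), transporters (4e-09), cyclic electron transport (7.15e-11), photosystem I and its antenna (0.0322, 2 of 12 higher, PSAO at 1.05 and PSAF at 1.00) and chlorophyll synthesis (0.0322, 0 of 11 called). None of the 5 was called with an estimated correlation (adjusted p = 0.198, 0.217, 0.33, 0.846 and 0.846).

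The other lists showed few calls between the species. Of the Calvin-Benson cycle, 4 of 17 members were higher (PDTPI at 1.29, PGK2 at 1.17, CP12-2 and GAPB) and 1 lower (CP12-3), while the Rubisco small subunit RBCS1A (AT1G67090) was at -0.69 (SE 0.10) and Rubisco activase RCA (AT2G39730) at -0.24 (SE 0.09), neither called. Of 21 photorespiration genes 1 was called, the glycine decarboxylase subunit GLDH2, at 2.22. Among 20 starch and sucrose genes 3 were higher (CYFBP at 2.34, SPS3F and APL1) and 2 lower (MEX1 at -1.68 and DPE2), and the list's median turned from 0.14 to -0.02 with library totals in place of TMM. The stomatal lineage genes MUTE (-1.84), TMM (-1.74) and EPF2 were the 3 lower of 9 epidermal genes, KNAT1 the lower and CUC3 (1.26) the higher of 18 leaf initiation genes. In cell division CYCB2;1 and KNOLLE were lower (2 of 25; the cyclin CYCB1;1, AT4G37490, at -0.50, SE 0.10). Clock genes RVE1 (1.57) and LHY (1.1) were higher (2 of 13), as were the senescence genes SAG12 and NAP (2 of 3) and PSBY (1 of 16 photosystem II genes). No member was called in chloroplast regulators, vein patterning, xylem and phloem markers or heat shock (0 of 13, 15, 8 and 6).

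In all, 1421 loci were higher and 1515 lower in rosea among 14779 tested. Of these, 544 were called higher and 523 lower at every one of the 8 stages. The largest differences among well-expressed loci included AT3G16150, an N-terminal nucleophile hydrolase, the histone deacetylase HD2C and the mitochondrial import receptor TOM20-1 on the higher side. On the lower side stood the polyamine oxidase PAO1 (-7.37, SE 0.13), the peroxidase PRXR1 (-7.30, SE 0.16) and the beta-amylases BAM5 (-6.72, SE 0.15) and BAM6 (-5.67, SE 0.12). PAO1 had 6.71 ± 2.52 CPM in rosea and 1098 ± 357 CPM in prostrata (n = 24 each). Reads of both species were counted at Arabidopsis loci, so differences of this size at single loci are uncertain. The share of calls that were higher was 48.4%, and 37.2% with library totals, which end the calls of PSAO, PSAF, GAPB, CP12-2, APL1 and LHY and call 3 photorespiration, 3 clock and 3 cell division genes lower.

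**Figure D2:**
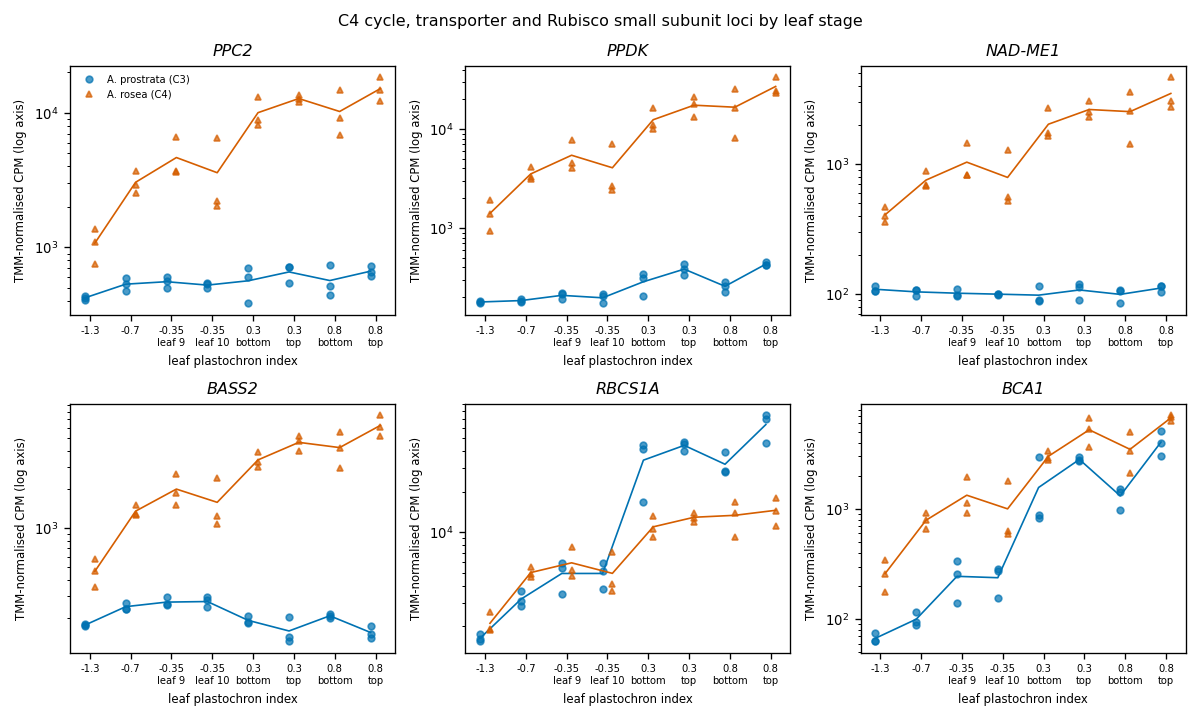
TMM-normalised CPM (log axis) of 6 genes by leaf plastochron index and leaf part in prostrata (circles) and rosea (triangles); each point is 1 library, n = 3 per group, and lines join group means. PPC2, PPDK, NAD-ME1 and BASS2 rise with age in rosea and stay low in prostrata, RBCS1A ends higher in prostrata, and BCA1 rises in both species.

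The youngest leaves, at 1 mm, were compared to see which differences were present from the start. PPDK was already higher in rosea by 2.98 (SE 0.34, adjusted p = 3.56e-09), NAD-ME1 by 1.91 (SE 0.28, adjusted p = 4.86e-07) and PPC2 by 1.35 (SE 0.31, adjusted p = 0.000634). NAD-ME2 stood at 0.95 (SE 0.23, adjusted p = 0.00105), just under the fold threshold. DIC1 was at 0.13 (SE 0.35) and was not called. PPC2 had 1072 ± 306 CPM in rosea and 422 ± 15.7 CPM in prostrata (n = 3 each).

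Of the C4 cycle enzymes 19 of 26 were higher at 1 mm, with RP1 at 3.46, ALAAT1 at 2.24, AMK2 at 2.1 and BCA1 at 1.95 (SE 0.41). BASS2 (1.38, SE 0.23), PPT2, DIT1, TPT and PPT1 were the 5 of 10 transporters that were higher. Cyclic electron transport had 12 of 16 members higher, with NDHL at 4.83 (SE 0.40), PNSL2 at 4.13, PNSL1 at 4.02 and PNSL3 at 3.47. Camera called the C4 cycle enzymes (adjusted p = 6.09e-08) and cyclic electron transport (6.63e-11); with an estimated correlation the adjusted p was 0.424 for both. RBCS1A (0.37, SE 0.28), RCA (0.25, SE 0.27) and CYCB1;1 (-0.23, SE 0.27) were not called. Elsewhere GLK1, a regulator of chloroplast genes, was higher at 1.76, the 4 Calvin-Benson genes CP12-2, RBCS3B, CP12-1 and SBPASE were higher and CP12-3 lower, and GLDH2 (1.69), EPF1 (1.1) and SAG12 (2.56) were the members called in photorespiration, epidermis and senescence. CYFBP and APL1 of the starch and sucrose list were higher, and of the clock genes LHY and RVE1 were higher and LUX lower. The remaining lists had 0 members called. Library totals end the calls of EPF1, SBPASE, APL1, PPT1 and PPCK2 at 1 mm and call 2 clock genes lower.

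At 1 mm, 1254 loci were higher and 1168 lower in rosea. AT2G38870, described as a serine protease inhibitor, had 24.9 ± 4.05 CPM in rosea and no count in prostrata, and was at least 310-fold higher in rosea over a floor of 3 counts per group. TOM6 (7.19, SE 0.48) and AT3G16150 (7.57, SE 0.25) were also among the most raised. The beta-amylase BMY3 had no count in rosea and was at least 138-fold lower there, and PAO1 (-7.39, SE 0.37), PRXR1 (-6.48, SE 0.42) and BAM5 (-5.28, SE 0.37) were again far lower.

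In the most mature tissue compared, the top parts at index 0.8, the C4 genes listed next differed more widely than at 1 mm. BCA1 differed less, and fewer C4 cycle enzymes were called higher. PPC2 was higher in rosea by 4.50 (SE 0.36, adjusted p = 2.59e-13), PPDK by 5.97 (SE 0.39), NAD-ME1 by 4.97 (SE 0.31) and NAD-ME2 by 4.28 (SE 0.26). ALAAT1 reached 6.21 (SE 0.42), BASS2 5.34 (SE 0.27) and DIC1 4.84 (SE 0.40). In the other direction RBCS1A was lower in rosea by -2.12 (SE 0.30, adjusted p = 1.51e-07) and RCA by -1.09 (SE 0.27, adjusted p = 0.000724). BCA1 was at 0.73 (SE 0.39, adjusted p = 0.114) and was not called.

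Here 14 of 26 C4 cycle enzymes were higher, with ASP4 (6.40) and ASP3 (6.06) beside ALAAT1, and 9 of 10 transporters, with DIC2 at 4.39 and DIC3 at 3.63. Photorespiration had 7 of 21 members lower and 1 higher: the glyoxylate aminotransferase AGT1 (-1.98, SE 0.25), the glycolate oxidases GOX1 (-1.61) and GOX2 (-1.69), the glycerate kinase GLYK (-1.64), the hydroxypyruvate reductase HPR1 (-1.48), GLDH3 and BOU were lower, and GLDH2 (2.17) was higher. Cell division genes were lower (15 of 25), including CYCB2;1 (-2.15), KNOLLE (-2.13), CYCB1;3 (-1.89) and CYCB1;1 (-1.29, SE 0.30). Of 9 epidermal genes 6 were lower, among them MUTE (-4.07, SE 0.61) and TMM (-3.79, SE 0.56); EPF2 had no count in the rosea tips against 1.1 ± 1.02 CPM in prostrata (n = 3 each). Camera called 7 lists: C4 cycle enzymes (adjusted p = 1.63e-10), transporters (6.11e-13), photorespiration (0.0424), photosystem I (0.0424, 2 of 12 higher), cyclic electron transport (0.000385, 11 of 16 higher), cell division (0.000785) and epidermis and stomata (0.00573). With an estimated correlation none was called (adjusted p = 0.119, 0.0822, 0.797, 0.797, 0.797, 0.797 and 0.768).

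Among lists that camera did not call in the tips, the Calvin-Benson cycle had 2 members higher (PDTPI and PGK2) and 4 lower (RBCS1A, RBCS3B, RCA and CP12-3), and starch and sucrose 6 higher and 2 lower (7 and 2 adjusted over the list alone), with SPS3F at 2.00 and SS1 at 1.71 against MEX1 at -1.90 and DPE2 at -1.64. The leaf initiation genes ETT (1.68), AIL6 (1.32), ARF4 and GRF5 were higher, and KNAT1 was lower, at 0.03 ± 0.05 CPM in rosea against 3.01 ± 1.19 CPM in prostrata. That list's median turned from 0.01 to -0.17 with library totals. Photosystem II had LHCB2.2 and PSBY higher and PSBS lower, chloroplast regulators SIG5 higher and HY5, CGA1 and FTSZ1 lower, and the clock RVE1, TOC1, LHY and LNK2 higher. SAG12 and NAP of senescence, MGP of vein patterning and SUC2 of the phloem were higher, and 0 of 6 heat shock genes were called. In total 1732 loci were higher and 2017 lower, with PRXR1 at -7.86 (SE 0.45) and BAM5 at -6.89 (SE 0.41) among the lowest and UGT78D3, AT2G21530 and TOM20-1 among the highest by fold. The share of calls that were higher was 46.2%, and 34.7% with library totals, which end the calls of PSAO, PSAF, PNSL1, LHCB2.2, PGK2, GBSS1, GRF5, SIG5, LNK2, MGP and SUC2 and call 2 C4 cycle enzymes and 16 cell division genes lower.

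The authors' deposited table holds fold changes between the species at 6 stages. They are given as prostrata over rosea, a direction checked against the counts, and their sign was reversed here. They stand beside the same counts that were used here, so a close match is no independent test. At 1 mm the authors' deposited table has 5408 loci with a q-value under 0.05, against 6225 loci with an adjusted p under 0.05 here, and 7321 against 8129 in the tops at index 0.8. Across loci, which are not independent replicates, Pearson's r of the fold changes in the authors' deposited table with those computed here was between 0.987 and 0.991 at the 6 stages. Every locus under 0.05 in both, 5164 at 1 mm and 7082 in the tops at index 0.8, had the same sign.

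To describe leaf maturation in the C3 species, leaf parts at index 0.8 were compared with 1 mm leaves. Photosynthesis genes rose in prostrata. RBCS1A rose by 4.79 (SE 0.32, adjusted p = 3.25e-15), BCA1 by 5.11 (SE 0.45) and RCA by 3.22 (SE 0.27). The C4-type genes NAD-ME1 (-0.05, SE 0.23), NAD-ME2 (-0.40, SE 0.20), BASS2 (0.02, SE 0.20), DIC1 (-0.45, SE 0.31), PPC2 (0.54, SE 0.27) and PPDK (0.90, SE 0.28) were not called. STM, a homeobox gene of the shoot meristem, fell and had 27.0 ± 1.58 CPM at 1 mm (n = 3) and 1 count over the 6 older libraries.

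Every tested member rose in photosystem I (12 of 12), photosystem II (16 of 16) and cyclic electron transport (16 of 16, with NDHL at 5.88, PNSL1 at 5.59, NDHN at 5.52 and PNSL2 at 5.51). The Calvin-Benson cycle had 16 of 17 members higher (RBCS3B at 4.94, HCEF1 at 3.67), photorespiration 20 of 21 (HPR1 at 4.03, PLGG1 at 3.78, GOX1 at 3.30), chlorophyll synthesis 9 of 11 (CHLM at 2.64) and chloroplast regulators 7 of 13 (GLK1 at 3.19, CGA1 at 2.81). Epidermal genes rose (7 of 9), including MUTE at 3.99 (SE 0.51) and EPF1 at 3.85. Leaf initiation genes fell (15 of 18, 1 higher), with AN3 at -4.54, ANT at -3.67 and GRF5 at -3.08, as did 7 of 25 cell division genes, led by MCM2 (-1.46) and MCM5 (-1.44), and 4 of 15 vein patterning genes, led by MP at -2.50. CYCB1;1 was at -0.66 (SE 0.23). Xylem and phloem markers SUC2, XCP2, XCP1 and VND7 were higher (4 of 8), starch and sucrose genes 6 higher and SUS4 lower, C4 cycle enzymes 8 higher and 1 lower, and transporters 3 higher (DIT1, TPT and PPT2).

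Camera called 14 lists in prostrata at the preset correlation, with adjusted p from 8.44e-22 for cyclic electron transport to 0.0181 for C4 cycle enzymes and for xylem and phloem. Leaf initiation was the 1 list called with an estimated correlation (adjusted p = 0.0171); that of cyclic electron transport was 0.0538 and those of the Calvin-Benson cycle and photorespiration 0.0558. Transporters (0.0846), heat shock (0.756; HSP17.6II lower, and 0 called over the list alone), senescence (0.783; RD20 higher, NAP lower) and clock (0.977; CCA1, RVE8 and LHY higher, TOC1 lower) were not called by camera. In all 2243 loci rose and 1224 fell, 64.7% higher. With library totals 23.0% of calls were higher, and the medians of C4 cycle enzymes (0.42), transporters (0.41) and clock genes (0.38) turned to -0.14, -0.14 and -0.16. On that scale the members called higher and lower were 3 and 3 of the C4 cycle enzymes, 2 and 2 of the transporters, 15 and 0 of the Calvin-Benson cycle, 17 and 0 of photorespiration, 3 and 0 of chlorophyll synthesis, 4 and 0 of the chloroplast regulators and 3 and 1 of starch and sucrose. They were 0 and 17 in cell division, 0 and 16 in leaf initiation, 0 and 11 in vein patterning, 3 and 0 in xylem and phloem, 4 and 0 in the epidermis, 0 and 2 in heat shock, 0 and 1 in senescence and 0 and 4 in the clock, and the calls of PPT2, VND7, RD20, CCA1, RVE8 and LHY ended. Among the largest changes, LTP2 rose by 5.64 (SE 0.38), and the cytochromes CYP78A10 (-9.08, SE 0.38), CYP712A1 and CYP78A5 (-6.22, SE 0.35) and TEL1 fell, as did LSH3 (-5.34) and LSH4 (-4.85).

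In rosea the C4 genes rose with maturation. PPDK rose by 3.92 (SE 0.34, adjusted p = 1.67e-12), PPC2 by 3.53 (SE 0.32), NAD-ME1 by 2.87 (SE 0.27), NAD-ME2 by 2.83 (SE 0.23), ALAAT1 by 4.06 (SE 0.36), BASS2 by 3.48 (SE 0.24) and DIC1 by 4.00 (SE 0.37). BCA1 rose by 4.22 (SE 0.43), RBCS1A by 2.73 (SE 0.28) and RCA by 2.26 (SE 0.26). CYCB1;1 fell, at -1.47 (SE 0.24), and STM had 26.3 ± 3.27 CPM at 1 mm (n = 3) and 2 counts over the 6 older libraries.

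All 10 transporters were higher in mature rosea leaves and 16 of 26 C4 cycle enzymes, while PCK1 (-2.25), PCK2 (-2.13) and PPC4 (-1.26) were lower. All members of photosystem I (12), photosystem II (16), cyclic electron transport (16; NDHN at 4.33, PNSB3 at 4.28) and chlorophyll synthesis (11; CRD1 at 2.39, CHLI1 at 2.32) were higher, as were 16 of 17 Calvin-Benson genes (HCEF1 at 3.30), 19 of 21 photorespiration genes (PLGG1 at 2.69), 9 of 13 chloroplast regulators and 16 of 20 starch and sucrose genes (APL1 at 3.09, SWEET11 at 2.52), with DPE2 lower. Cell division fell in 23 of 25 members (CDKB2;2 at -1.81, KNOLLE at -1.70) and leaf initiation in 12 of 18 (AN3 at -4.57, ANT at -3.60). In the epidermal list CER3 was higher and TMM (-1.63), SPCH (-1.23), EPF2 and FDH were lower. The vein patterning genes that were higher included JKD and MGP and those that were lower included MP (-2.33) and SCR, and SUC2, XCP2, XCP1 and APL were the 4 of 8 xylem and phloem markers that were higher. HSP17.6II was lower, RD20 was higher, and of the clock genes 5 were higher and GI lower.

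Camera called 14 lists in rosea, from cyclic electron transport (adjusted p = 3.34e-17) to vein patterning (0.00929), but not the epidermal list (0.562), heat shock (0.646), senescence (0.486) or the clock (0.218). Leaf initiation was again the 1 list called with an estimated correlation (adjusted p = 0.025); transporters were at 0.0669 and C4 cycle enzymes at 0.122. In total 2211 loci rose and 1517 fell, 59.3% higher. Library totals gave 6253 calls with 17.0% higher, and turned the medians of senescence (0.45) and clock genes (0.45) to -0.22 and -0.24. On that scale the members called higher and lower were 15 and 8 of the C4 cycle enzymes, 8 and 0 of the transporters, 15 and 0 of the Calvin-Benson cycle, 14 and 0 of photorespiration, 7 and 0 of chlorophyll synthesis, 2 and 0 of the chloroplast regulators and 6 and 1 of starch and sucrose. They were 0 and 25 in cell division, 0 and 14 in leaf initiation, 0 and 9 in vein patterning, 2 and 0 in xylem and phloem, 0 and 4 in the epidermis, 0 and 2 in heat shock, 0 and 0 in senescence and 0 and 2 in the clock, and the calls of JKD, MGP, RD20, CER3, XCP1 and APL ended. FAD5 (4.48, SE 0.39), ZIP10 (4.46, SE 0.78) and the extensin-like AT1G23720 (4.67, SE 0.55) were among the named loci that rose most, and CYP78A10 (-6.98, SE 0.38), TEL1, IAMT1 (-6.40) and CYP78A5 (-5.93) fell. Between the species, 1411 loci rose in both, against 336 if the lists were independent, and 670 fell in both, against 126. A further 36 rose in prostrata and fell in rosea and 24 fell in prostrata and rose in rosea. Across the 14779 loci, which are not independent replicates, Pearson's r of the changes was 0.695.

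**Figure D3:**
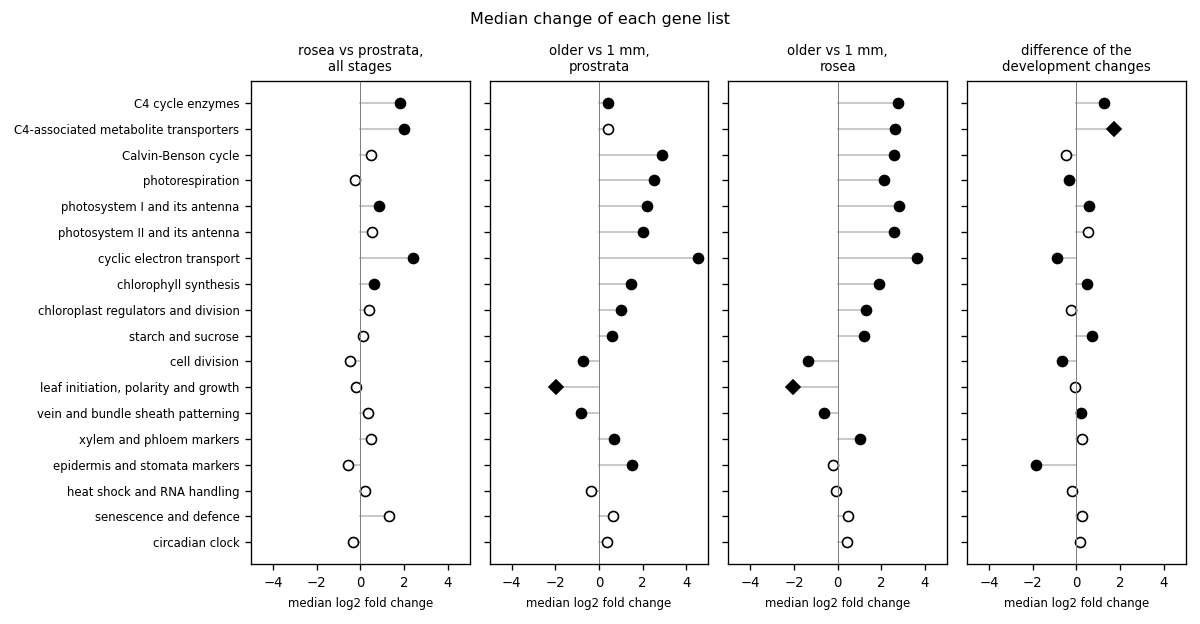
Median log2 fold change (x axis) of the 18 gene lists in 4 contrasts; filled symbols mark lists called by camera at the preset correlation and diamonds those also called with an estimated correlation (leaf initiation in both species, transporters in the difference). With library totals in place of TMM the medians of starch and sucrose in the first panel, of C4 cycle enzymes, transporters and clock genes in the second, and of senescence and clock genes in the third change sign.

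The change with age was then compared directly between the species, as the rosea change minus the prostrata change. The C4 genes rose more in rosea: DIC1 by 4.45 (SE 0.45, adjusted p = 1.98e-09), BASS2 by 3.45 (SE 0.29, adjusted p = 2.26e-11), NAD-ME2 by 3.22 (SE 0.29), PPDK by 3.02 (SE 0.40), PPC2 by 2.99 (SE 0.39) and NAD-ME1 by 2.92 (SE 0.34). RBCS1A rose less in rosea (-2.06, SE 0.35, adjusted p = 2.97e-05). BCA1 (-0.89, SE 0.48), RCA (-0.96, SE 0.33) and CYCB1;1 (-0.80, SE 0.34) were not called. Stomatal lineage genes diverged with age, with MUTE at -3.94 (SE 0.87), EPF1 at -3.05 and TMM at -2.67 (SE 0.57).

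The transporters were the 1 list that camera called both at the preset correlation (7 of 10 higher, adjusted p = 1.61e-16) and with an estimated one (adjusted p = 0.0274), with DIC2 at 4.54 and DIC3 at 4.26 beside DIC1; these 3 loci moved in parallel and are uncertain as single loci. C4 cycle enzymes had 14 of 26 members higher and 5 lower (adjusted p = 3.96e-05), with ASP3 at 4.51, ASP2 at 4.38, ASP4 at 4.06 and ALAAT1 at 3.67 against PCK1, PCK2, NADP-MDH, PPCK1 and PPCK2, and epidermis and stomata had 7 of 9 lower (9.36e-08). Camera also called cell division (0.000398, 4 lower, among them CYCB2;1 at -1.40 and KNOLLE at -1.32), cyclic electron transport (0.00638, 5 lower and NDHS higher, 7 and 1 over the list alone, PNSL1 at -2.48), photorespiration (0.0137, 5 lower, HPR1 at -1.80, AGT1 at -1.61), photosystem I (0.027, 0 called), vein patterning (0.0401, 0 called), chlorophyll synthesis (0.045, 0 called) and starch and sucrose (0.045, 3 higher and 1 lower, 4 and 1 over the list alone). With an estimated correlation the adjusted p was 0.538 for C4 cycle enzymes, 0.0636 for epidermis and stomata and 0.702 for the other 7. The rest were not called: Calvin-Benson cycle (0.111, PDTPI higher, RBCS1A and RBCS3B lower), photosystem II (0.108), chloroplast regulators (0.797, SIG6 higher, CGA1 and GLK1 lower), leaf initiation (0.949, GRF5, ETT and ARF4 higher, KNAT1 lower), xylem and phloem (0.213), heat shock (0.949), senescence (0.655, NAP higher) and clock (0.0966, TOC1 higher).

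The fold changes given next average bottom and top parts at index 0.8, while the levels of older leaves are those of the tops alone. Among the largest single differences, the glycosyl hydrolase AT4G19720 (6.21, SE 0.44) fell in prostrata from 32.2 ± 4.83 to 0.42 ± 0.15 CPM in the tops and stood at 1.58 ± 0.45 and 3.73 ± 0.66 CPM in rosea (n = 3 each). The lipid transfer protein LTP4 (-4.46, SE 0.32) went from 15.1 ± 2.23 to 498 ± 79.8 CPM in prostrata tops and from 13.9 ± 3.36 to 16.1 ± 3.66 CPM in rosea. AZI1 (5.49, SE 0.65), the asparagine synthetase ASN1 (4.83, SE 0.61) and XTH6 (4.35, SE 0.54) had a more positive change in rosea. LTP2 (-4.86, SE 0.45), the cuticle regulator SHN1 (-4.56, SE 0.56) and IAMT1 (-3.63, SE 0.79), which fell in both species, had a more negative one. In all, the change was more positive in rosea than in prostrata at 667 loci and more negative at 943. The share with a more positive change was 41.4%, and 28.4% with library totals, which end the calls of PPT2, SIG6, ETT, ARF4 and TOC1 and call 8 cyclic electron transport, 7 photorespiration, 6 C4 cycle, 5 cell division, 3 Calvin-Benson, 3 chloroplast regulator and 2 starch and sucrose genes more negative.

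**Figure D4:**
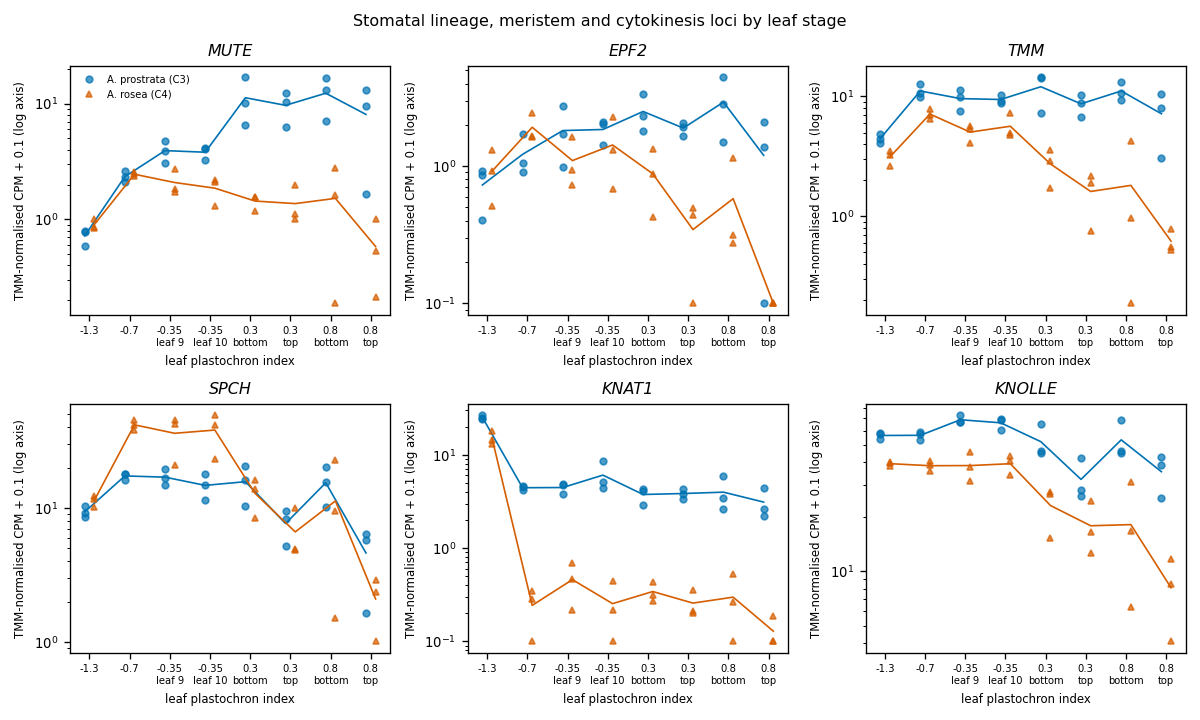
TMM-normalised CPM plus 0.1 (log axis) of 6 genes by leaf plastochron index and leaf part in prostrata (circles) and rosea (triangles); each point is 1 library, n = 3 per group, and lines join group means. MUTE, EPF2 and TMM of the stomatal lineage are lower in rosea than in prostrata in divided leaves, SPCH is lower in top than in bottom parts of both species, and KNAT1 is near 0 in rosea beyond 1 mm.

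Top and bottom parts of divided leaves were compared over indices 0.3 and 0.8 as unpaired samples, since a pairing by replicate number was not shown. A block for each leaf number within a leaf length was fitted on the divided leaves of each species alone. There edgeR called 0 loci in prostrata and 0 in rosea, with 2972 and 1841 at an unadjusted p under 0.05. The same libraries without the block also gave far fewer calls than the full fit, as given below, so the fall is not due to the block alone. The calls below rest on the fit of all 48 libraries without that block. In prostrata the loci that were higher in tops included the plastid-encoded RBCL (ATCG00490) at 1.46 (SE 0.41, adjusted p = 0.0154), PSAB at 1.42 (SE 0.41), ATPI at 1.4 (SE 0.27), PSBB at 1.34 (SE 0.32) and PSAA at 1.3 (SE 0.40). All plastid loci together held 0.034% to 0.075% of the counts in bottom parts and 0.063% to 0.124% in tops. Whether these loci moved singly or with this small plastid share was not tested. BCA1 was higher by 1.23 (SE 0.28, adjusted p = 0.00339) and the cytosolic fructose bisphosphatase CYFBP by 1.43 (SE 0.21). SPCH, the transcription factor that starts the stomatal lineage, was lower in tops (-1.38, SE 0.34, adjusted p = 0.0062), as were the expansin EXPA11 (-1.51), the lipase GLIP7 (-1.88, SE 0.26) and GRF5 (-1.23). ATMG00280, a mitochondrial locus described as a Rubisco large chain, was at 1.36 and is uncertain as a locus of its own beside RBCL.

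Few list members passed the fold threshold in prostrata tops: BCA1, CYFBP and NDHN (1.02) were higher and GRF5 and SPCH lower. RBCS1A was at 0.67 (SE 0.20), RCA at 0.86 (SE 0.19), PPC2 at 0.23, PPDK at 0.58, NAD-ME1 at 0.15, NAD-ME2 at 0.17, BASS2 at -0.35, DIC1 at -0.21 and CYCB1;1 at -0.45, none of them called. Camera called 13 lists at the preset correlation, with photorespiration at a median of 0.72 (adjusted p = 8.71e-21), cyclic electron transport at 0.68 (1.95e-11), Calvin-Benson cycle at 0.68 (1.01e-11), starch and sucrose at 0.54 (2.09e-12) and cell division at -0.61 (7.54e-15). It called 0 lists with an estimated correlation (adjusted p = 0.123 for each of these). Transporters, vein patterning, epidermis, heat shock and senescence were not called at either setting. In all 64 loci were higher and 116 lower in prostrata tops, 35.6% higher. The share was 18.6% with library totals, which end the call of NDHN and call 3 leaf initiation genes and 1 cell division gene lower, and 52.3% with limma-voom.

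The library labelled 15 mm bottom replicate 1 of prostrata differed little from 15 mm top replicate 1, at a chi-square of 1.15 per degree of freedom over 13413 loci, while the other pairs of a bottom and a top library of these leaves ran from 25.0 to 80.0. Without it 141 loci were higher and 197 lower in tops, and 176 of these 338 were among the 180. Photorespiration then had 5 members higher, among them GLDP2 at 1.16 and PLGG1 at 1.08, cyclic electron transport 4, with PNSL1 at 1.2 and NDHL at 1.1, and the Calvin-Benson cycle 3, PRK at 1.09, RCA at 1.07 and RPI3 at 1.02. Leaf initiation had 4 members lower, among them AN3 (-1.15) and ANT (-1.07). Camera still called 13 lists, and 0 with an estimated correlation (lowest adjusted p = 0.0805). The count was 379 without both of these libraries, 98 without replicate 3 of the 15 mm bottom parts and 276 without replicate 1 of the 18 mm bottom parts. Fitted on the divided prostrata leaves alone it was 2. Leaving out single libraries was chosen after seeing the data.

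In rosea tops the chitinase CHIA (1.45, SE 0.30, adjusted p = 0.00536), the glucanase BG3 (1.38, SE 0.36) and the light-signalling gene HYH (1.27, SE 0.33) were higher. SPCH (-1.70, SE 0.37, adjusted p = 0.0063), the metal pumps HMA4 (-1.25, SE 0.32) and HMA2 (-1.16, SE 0.30) and the auxin-conjugating enzymes GH3.1 (-1.15, SE 0.21) and GH3.3 (-1.10, SE 0.18) were lower. EPF2 was the other epidermal gene called lower (3 of 9 adjusted over the list alone), and no other list member was called. PPC2 (0.46, SE 0.22), PPDK (0.59), NAD-ME1 (0.42), NAD-ME2 (0.39), BASS2 (0.51, SE 0.16), DIC1 (0.56), BCA1 (0.87, SE 0.28), RBCS1A (0.18), RCA (0.31) and CYCB1;1 (-0.69, SE 0.20) were not called. Camera called 14 lists, with cell division at a median of -0.47 (adjusted p = 1.15e-16), cyclic electron transport at 0.45 (1.35e-07), C4 cycle enzymes at 0.44 (8.59e-07) and transporters at 0.44 (4.33e-06); with an estimated correlation 0 were called (adjusted p = 0.257 for each of these). Vein patterning, xylem and phloem, heat shock and senescence were not called, and the senescence median turned from 0.05 to -0.08 with library totals.

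In rosea 22 loci were higher and 64 lower in tops, 25.6% higher, and 11.9% with library totals, which call 1 leaf initiation gene lower. The count of 86 fell to 47 without replicate 3 of the 11 mm bottom parts, 40 and 52 without replicates 1 and 2 of the 11 mm top parts, and 31 without replicate 2 of the 13 mm bottom parts. It rose to 162 without replicate 3 of the 11 mm top parts and 199 without replicate 3 of the 13 mm bottom parts. Fitted on the divided rosea leaves alone it was 17. Between the species, 2 loci were higher in both tops (AT1G51340 and AT2G15020) against 0.1 for independent lists, and 14 were lower in both against 0.5, among them SPCH, LSH6, LSH10 and MLP28, named after their values were seen. The difference between the parts differed between the species at 17 loci, 10 more positive and 7 more negative in rosea. These included the terpene synthase TPS21 (-3.28, SE 0.61, adjusted p = 0.0139) and GLIP7 (1.88, SE 0.36, adjusted p = 0.0139). Without the library labelled 15 mm bottom replicate 1 of prostrata the count was 50, all 17 among them.

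Leaf 9 and leaf 10 were compared at 7.5 mm to see whether node position mattered. In edgeR 0 of 14779 loci were called in prostrata and 0 in rosea. At an unadjusted p under 0.05 and without a fold threshold there were 153 and 252 loci, fewer than the 5% of loci expected with no change, so this unpaired test says little about node position. DESeq2 called 2 loci higher in leaf 10 of prostrata, the lipid transfer protein LTP2 (1.80) and AT2G24810 (1.26), and 1 lower in rosea, AT4G25890 (-1.60); limma-voom called AT2G24810 (1.28) in prostrata and 0 in rosea. These names were chosen after their values were seen. Each leaf 10 library was closest in counts to the leaf 9 column of its own number, although the labels number the leaf 9 samples differently. With a block by that number, chosen after seeing the data, edgeR called 5 loci in prostrata (LTP2, AT2G24810, AT1G35550, CYP78A5 and CYP78A10) and 9 in rosea. CYP78A10 and CYP78A5, like STM, fall steeply with age, while LTP2, also higher in leaf 10, rises with age in prostrata. Node position and leaf age are thus not separated here. Without a block, the cytochrome CYP78A10 was called in prostrata without replicate 2 (2.09) or 3 (2.11) of leaf 10, but not without replicate 1, so these calls rest on that library. In prostrata camera called 0 of the 18 lists. STM was the 1 member of the leaf initiation list higher in leaf 10 when adjusted over the list alone, at 2.2 ± 2.28 CPM against 0.49 ± 0.18 CPM in leaf 9 (n = 3 each). Its leaf 10 libraries were at 4.83, 0.80 and 0.97 CPM, so this value rests on replicate 1, and without replicate 1 of both leaves the log2 fold change was 0.64. In rosea camera called 14 lists at the preset correlation, 12 lower in leaf 10 and 2 higher: cyclic electron transport (median -0.39, adjusted p = 1.59e-09), photosystem I (-0.30, 3.27e-05) and transporters (-0.25, 5.94e-05) were lower and cell division (0.14, 0.00779) and leaf initiation (0.12, 0.0272) higher. With an estimated correlation 0 were called (adjusted p = 0.347, and 0.554 for cell division). These list tests had no block, and none was run with the block by column number.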

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

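The test of a bottom library holding the RNA of a top part, and the check of which libraries the other splits kept together, were chosen only after results were seen; the other tests in this part were set out beforehand. The change with leaf age differed between the species at 1610 loci in the test of the difference itself. The C4 genes rose more in rosea than in prostrata, on the log2 scale by 4.45 for DIC1, 3.45 for BASS2, 3.22 for NAD-ME2, 3.02 for PPDK, 2.99 for PPC2 and 2.92 for NAD-ME1, and RBCS1A rose less (-2.06). Camera on this difference called transporters of C4 metabolites (median 1.72), C4 cycle enzymes (1.27), starch and sucrose (0.70), photosystem I (0.60), chlorophyll synthesis (0.48) and vein patterning (0.23) as more positive in rosea. Epidermis and stomata (-1.85), cyclic electron transport (-0.88), cell division (-0.64) and photorespiration (-0.33) were more negative, where the epidermal median is that of HTH and is not moved by the low counts of EPF2. With an estimated correlation the transporters alone were called (adjusted p = 0.0274).

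The difference between leaf parts differed between the species at 17 loci, and camera called 7 lists in it at the preset correlation. Transporters (median 0.45) were more positive in rosea. Photorespiration (-0.39), Calvin-Benson cycle (-0.37), xylem and phloem (-0.29), starch and sucrose (-0.25), cyclic electron transport (-0.23) and chlorophyll synthesis (-0.19) were more negative. None of the 7 was called with an estimated correlation (adjusted p = 0.579 for transporters and photorespiration, 0.566 for xylem and phloem and 0.768 for the others).

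Other splits of the same libraries were fitted for each count of calls. The real grouping alone was as large for the species over all stages (2936 calls, 1 of 25 splits as large, highest other 0), and for the change with age in prostrata (3467, 1 of 25, 1097) and in rosea (3728, 1 of 25, 1775). That share lies under the 0.05 set beforehand and is the lowest that 25 splits can give. In the species comparison the other splits mixed the species within groups, which widens the fitted spread, so their count of 0 says little. The other splits of the age comparisons mixed 1 mm and older leaves within groups, so the same limit holds for their counts. For the leaf parts of rosea 1 of 25 splits was as large (86, highest other 67), which reaches that share for this unpaired count only. The count fell below 67 without replicate 3 of the 11 mm bottom parts (47), replicates 1 (40) or 2 (52) of the 11 mm top parts or replicate 2 of the 13 mm bottom parts (31). It rose to 162 without replicate 3 of the 11 mm top parts and 199 without replicate 3 of the 13 mm bottom parts. It was 17 when fitted on the divided rosea leaves alone. With a block for each leaf number added to that fit it was 0 in edgeR (1841 loci at an unadjusted p under 0.05). A difference between these parts is therefore not settled. Chance was not excluded for the leaf parts of prostrata (180, 2 of 25, 229). The share was not under 0.05 either for the difference of the age changes (1610, 2 of 25, 3469) or of the leaf parts between the species (17, 3 of 25, 208). For these differences the splits exchanged species labels within each stage. An uneven exchange turns the difference between the species into a difference of changes, so these splits cannot decide on chance. In the difference of the age changes, the 3 other splits with any call (3469, 1469 and 1061) each kept all 3 rosea libraries of 1 mm leaves on one side, which points to a structure of the samples, the difference between the species. For 1 mm leaves (2422, highest other 0) and mature tips (3749, 115) the 10 splits are too few for a share under 0.05. For leaf 10 against leaf 9 the count was 0 in each species, so each of the 10 splits was as large whatever the grouping and the splits decide nothing; the highest other was 1 in prostrata and 104 in rosea.

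Among loci with a mean of at least 10 CPM in a species, 27 stood at least 32-fold apart between the species on average, 16 higher in rosea and 11 higher in prostrata. Reads of 1 gene counted at different paralogs in each species would be made up by other loci of the family; over the 19 loci with a described family the median share made up was 0.076, with bounds from -0.903 to 1.32 that leave this open. A weaker match of 1 species' sequence to the Arabidopsis reference would act alike at every age, and 14.8% of the 27 loci (4, bounds 4.2 to 33.7) changed differently with age, which also leaves it open. In simulation the share was 0.986 where reads had moved between paralogs and 0.027 where they were lost. The simulated families were all of 1 size, and their other loci hardly differed between the species. At the real loci the share ran from -24.1 (BMY3) to 31.4 (AT1G55260), so the separation in simulation does not carry over to them. A real difference between the species stays open as well and was not tested, so these cannot be told apart.

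Divided leaves gave few calls between top and bottom, 180 in prostrata and 86 in rosea, beside a wide spread between replicates. Replicates at different developmental states would deviate along the change with age, but the median absolute r across genes, which are not independent replicates, was 0.216 over the 24 divided-leaf libraries (bounds 0.13 to 0.265), below the 0.3 set beforehand, which argues against this as the whole cause. It stays open as a part of it: the median was 0.034 in 1 mm libraries and 0.153 in other whole leaves, and 6 of the 24 libraries were at 0.3 or more, up to 0.517. For sequencing depth, the deviation along age against that of the total gave a Pearson's r of -0.046 (permutation p = 0.868) and a Spearman's rho of -0.09 (p = 0.737) over these libraries, and -0.053 without the 2 farthest, with bounds from -0.432 to 0.314 that leave depth open. A candidate explanation in prostrata is a bottom library that holds the RNA of a top part: the chi-square per degree of freedom between bottom and top libraries 1 of 15 mm leaves was 1.15, below the lowest between replicates (1.21), and without the bottom library the count was 338. A real difference between the parts, mostly under the fold threshold, stays open: 2079 and 700 loci passed the adjusted p alone in the unpaired test.

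The carriers DIC1, DIC2 and DIC3 changed in parallel, as did the aminotransferases ASP2 and ASP3. Reads of 1 gene spread over its paralogs would keep their ratio constant, and the SD of the log2 ratio over the 24 rosea libraries was 0.055 for DIC1 to DIC2, 0.112 for DIC1 to DIC3 and 0.056 for ASP2 to ASP3, all under the 0.5 set beforehand. In prostrata these SDs were 0.139, 0.156 and 0.155. The parallel changes may therefore be those of fewer genes than loci, and close co-regulation of separate genes, not tested here, stays open.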

How the results depend on the processing

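Leaving out single libraries of divided leaves, leaving out the 15 mm libraries 1 of prostrata, and a block by column number were chosen only after results were seen; the other alternatives were planned. No call of a named gene changed direction under the alternatives run. Over 923 pairs of a named gene and a comparison, 11044 of 11435 values under an alternative kept their side of the threshold. A further 140 came past the threshold and 251 fell short of it. Changes of sign in genes called under neither setting were not counted. Counts between the species and with age stayed within 1.5 times with DESeq2, limma-voom, DESeq2's size factors, no filter, without the 50 highest loci, and when fitted on the groups compared. Depth limits rare transcripts: the floor of 3 counts per group leaves differences below it undetectable. Replicates 1 and 2 of 1 mm prostrata leaves, the closest replicates, were counted as separate samples, and without the first of them 2344 loci were called at 1 mm, 3424 with age in prostrata and 1505 in the difference of the age changes. The alternatives planned for the F1 hybrid and for index 1.5 were not run, and those on a pseudocount did not apply.

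With the adjusted p alone as threshold, 11925 loci were called between the species over the stages, 6225 at 1 mm, 8129 in mature tips, 9099 with age in prostrata and 8916 in rosea, 3721 in the difference of the age changes, 2079 and 700 between the leaf parts of prostrata and rosea, and 35 in the difference of the leaf parts. The filter of 10 CPM in 3 libraries, which tests fewer loci, gave 1659, 1269 and 2356 between the species over the stages, at 1 mm and in tips, and 100 and 52 between leaf parts. Library totals gave 6253 with age in rosea; the shift of all loci on that scale shows the cause. Fitted on the divided leaves alone, the leaf parts gave 2 calls in prostrata and 17 in rosea. Without 1 replicate number throughout they ranged from 40 to 400 in prostrata and from 12 to 335 in rosea. Single libraries mattered too: leaving out 1 gave 98 to 338 in prostrata and 31 to 199 in rosea. Without the library labelled 15 mm bottom replicate 1 of prostrata the count was 338, and 50 in the difference of the parts; without the top library as well these were 379 and 40. The cause of the other moves was not tested.

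Leaf 10 against leaf 9 of prostrata, with 0 calls, gave 2 with DESeq2 and 1 with limma-voom, and from 0 to 1 without 1 replicate; rosea gave 1 with DESeq2. With an estimated correlation camera called 0 lists in place of 5 between the species over the stages, 0 in place of 2 at 1 mm, 0 in place of 7 in tips, 1 in place of 14 with age in each species, 1 in place of 10 in the difference of the age changes, 0 in place of 13 and 14 between leaf parts, and 0 in place of 14 in leaf 10 of rosea.

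A pairing of the samples by replicate number was not shown. Deviations of libraries with the same number had a median r of 0.007 over 91 pairs of groups (lowest -0.573), and in 2 of these pairs, and 1 of the 4 pairs of leaf parts, every r was over 0.1. Between bottom and top parts of 1 leaf length r ran from -0.441 to 0.405, and it was 0.201, 0.313 and 0.384 in 18 mm prostrata leaves. These values do not exclude that bottom and top parts of the same number came from the same leaves. With the replicate number as a block the counts were 2927 between the species, 2414 at 1 mm, 3714 in tips, 3448 and 3724 with age, 1580 in the difference and 173 and 81 between leaf parts. A block for each leaf number within a leaf length gave 0 in edgeR in prostrata and 0 in rosea, with 2972 and 1841 loci at an unadjusted p under 0.05. That fit used the divided leaves of each species alone, which gave few calls without the block too. Other tools were not run with it. As a hint from the data, each of the 6 leaf 10 libraries was closest, by chi-square per degree of freedom, to the leaf 9 column of its own number (1.82 to 3.19 in prostrata, 2.94 to 9.39 in rosea). A block by that number gave 5 calls in prostrata (LTP2, AT2G24810, AT1G35550, CYP78A5 and CYP78A10) and 9 in rosea.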

Other observations

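The tests of families, and the choice of loci that changed sign, came after the results were seen. Between the species 118 loci were called higher in rosea at some stage and lower at another. The abscisic acid synthesis genes NCED3 and NCED9 were higher in rosea at 1 mm (1.60, SE 0.64, adjusted p = 0.0427, and 1.45, SE 0.59, adjusted p = 0.0449 in edgeR) and lower in the mature tips (-1.72, SE 0.63, and -1.87, SE 0.56). STOMAGEN, a peptide that promotes stomata, went from 1.05 (SE 0.39) to -1.77 (SE 0.32), and the Rubisco small subunit RBCS3B from 1.4 (SE 0.30) to -1.07 (SE 0.29). In the other direction the asparagine synthetase ASN1 went from -1.19 (SE 0.48) to 3.72 (SE 0.51), the sulfate assimilation enzyme APR2 from -1.23 (SE 0.33) to 1.37 (SE 0.33) and the cytochrome CYP78A6 from -1.31 (SE 0.24) to 1.77 (SE 0.31).

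Families of at least 10 loci with a shared description were tested with camera, 175 in all, adjusted over the families. Xyloglucan endotransglucosylases, which remodel the cell wall, were higher in rosea over the stages in 13 of 18 members (median 1.43, adjusted p = 0.000184; adjusted p = 0.847 with an estimated correlation). Beta-glucosidases were lower in rosea at 1 mm in 15 of 23 members and higher in 1 (median -1.59, adjusted p = 8.82e-13; 0.0756 with an estimated correlation). MATE efflux carriers had a more positive change with age in rosea in 12 of 29 members (median 0.61, adjusted p = 8.51e-09; 0.0786 with an estimated correlation), and 3-ketoacyl-CoA synthases, which elongate fatty acids, a more negative one in 6 of 15 (median -0.83, adjusted p = 8.74e-08; 0.556 with an estimated correlation). Histones were lower in rosea tips in 14 of 20 members (median -1.23, adjusted p = 0.00181; 0.976 with an estimated correlation). Auxin response factors fell with age in 10 of 15 members in prostrata (median -1.16, adjusted p = 1.43e-05; 0.499 with an estimated correlation) and in 9 of 15 in rosea (median -1.41, adjusted p = 5.81e-07; 0.441 with an estimated correlation).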
